A study of Mus musculus with 2 samples.

How the data were processed

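The data are 2 Affymetrix expression arrays of mouse cells, hybridised with biotin-labelled RNA. CD11c+ cells were sorted by flow cytometry from the lamina propria of the small intestine of C57BL/6 mice. CD11b-negative cells were hybridised to 1 array and CD11b-positive cells to the other. Total RNA was taken with a column kit and treated with DNase, per the labels' protocols. How many mice or sorts went into each RNA is not given in the sources used here.

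The deposited table holds 1 value per probe set and array, on the log2 scale, rounded to 2 decimals. The authors made these log2 values with RMA (robust multi-array averaging, which corrects background, equalises the arrays' distributions and summarises the probes of a set) in the Affymetrix Expression Console, per the submitters' processing notes. Software versions and the annotation used at that step are not given in the sources used here. The log2 scale was inferred from the method named and from the values, which ran from 2.93 to 14.29 on the CD11b-negative array and from 2.89 to 14.15 on the CD11b-positive array. The medians were 6.21 and 6.22 and the 75th percentiles 7.97 and 7.90, so the deposited arrays were already close in distribution. RMA sets a shared scale, so a difference that shifted all genes alike would not be seen. It also compresses differences of dim probe sets, so a fold against a value near the low end is more likely too small than too large. The table carries no detection calls.

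Probe sets were named from GEO's platform annotation, with symbols checked through the gene ID against RefSeq's table for assembly GRCm38.p6, which was used for names only. Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 carried none in that table. The gene ID of 21698 of the single-gene probe sets was found in the RefSeq table, and no symbol needed an update. Probe sets with 1 symbol gave 19938 genes. For the 999 genes with more than 1 probe set, the probe set with the highest mean of both arrays was taken. Probe sets with several symbols or none entered no comparison of genes or gene lists, and only their counts at least 2-fold apart are given, among the additional observations.

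Every difference is the log2 value of the CD11b-positive array minus that of the CD11b-negative array, and a fold is 2 to the power of its size. With 1 array per group there is no replicate, no standard error and no p-value, and no difference has a replicate check. The number of arrays limits the precision. As a measure of technical scatter, the 643 genes with at least 2 probe sets past the low filter were used. The differences of 2 probe sets of a gene scattered with an SD of 0.19 (log2) per probe set, which leaves out all variation between animals, sorts and hybridisations. A gene passed the low filter if the higher of its values was at or above 6.21, the median of all values of both arrays. Counts of genes at least 2-fold apart are descriptions of these arrays.

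Before the data were examined, 28 gene lists were fixed with 595 members in all, of which 548 were measured. They covered dendritic cell and macrophage types, other cell types that the sort could hold, and functions of myeloid cells. The median difference of each list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart where its percentile was under 2.5 or over 97.5. Of 28 lists, 1.4 are expected there by chance if members were independent, which genes of a list are not. Named genes were the 12 with the largest difference in each direction past the low filter, 21 genes fixed by name, and for each list the 2 members with the largest difference and the 2 with the highest mean. Provisional symbols and immunoglobulin or T cell receptor segments were left out of the first part of this rule. Other list members are named where a sentence needs them. Of the 21 fixed genes, 20 were measured, and Tlr5 was not analysed here.

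On a simulated pair of arrays built on the 19938 genes of this comparison, with scatter taken from the middle of the real differences, 98.0% of 100 genes changed by 1.5 (log2) and all of 100 genes changed by 2 passed the 2-fold threshold. Of 400 unchanged lists of 20 genes, 5.0% stood apart, and all of 100 lists shifted by 0.3 did. The simulated scatter was independent between genes and of the same size at every level, and changes were planted only in genes above the low filter. These shares therefore check the code and say nothing about variation between animals, sorts or hybridisations. Alternatives tried were median centring, quantile normalisation, removal of a lowess trend (fraction 0.3, 3 iterations), the mean of a gene's probe sets, other low filters, thresholds of 1.5-fold and 4-fold, and other ways of scoring the lists. Leaving Itgam out of the Fc receptor and complement list was added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.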

Results

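Gene expression was measured in 2 populations of freshly isolated CD11c+ cells from the small intestinal lamina propria of C57BL/6 mice, the connective tissue under the gut epithelium. CD11c is an integrin chain carried by dendritic cells and also by many intestinal macrophages. The cells were divided by CD11b, another integrin chain, and each population was profiled on 1 array. The sample titles call both populations dendritic cells. The comparison asks how the transcript profiles of CD11b-negative and CD11b-positive CD11c+ cells differ. All values are log2 RMA values from a single array per population, so no value has an error from replicates and no test between the populations could be made. Across the 19938 genes the arrays correlated with r = 0.976, which is a correlation across genes, and genes are not independent replicates.

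The sorted proteins' own transcripts followed the labels. Itgam, which encodes CD11b, was 6.31 on the CD11b-negative array and 9.16 on the CD11b-positive array, a 7.21-fold difference. Itgax, which encodes CD11c, was 11.06 and 11.33. Because the cells were sorted on CD11b, the Itgam difference checks the labels only.

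The CD11b-positive array was marked by genes of macrophages, and the CD11b-negative array by genes of type 1 conventional dendritic cells. Of the 10870 genes past the low filter, 371 were at least 2-fold higher on the CD11b-positive array and 163 at least 2-fold higher on the CD11b-negative array. At 1.5-fold the counts were nearly even, at 752 and 718, while at 4-fold they were 111 and 25 and at 8-fold 51 and 9. Among genes past the filter the quartiles of the difference were -0.27 and 0.15 (log2), with a median of -0.06.

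**Figure D1:**
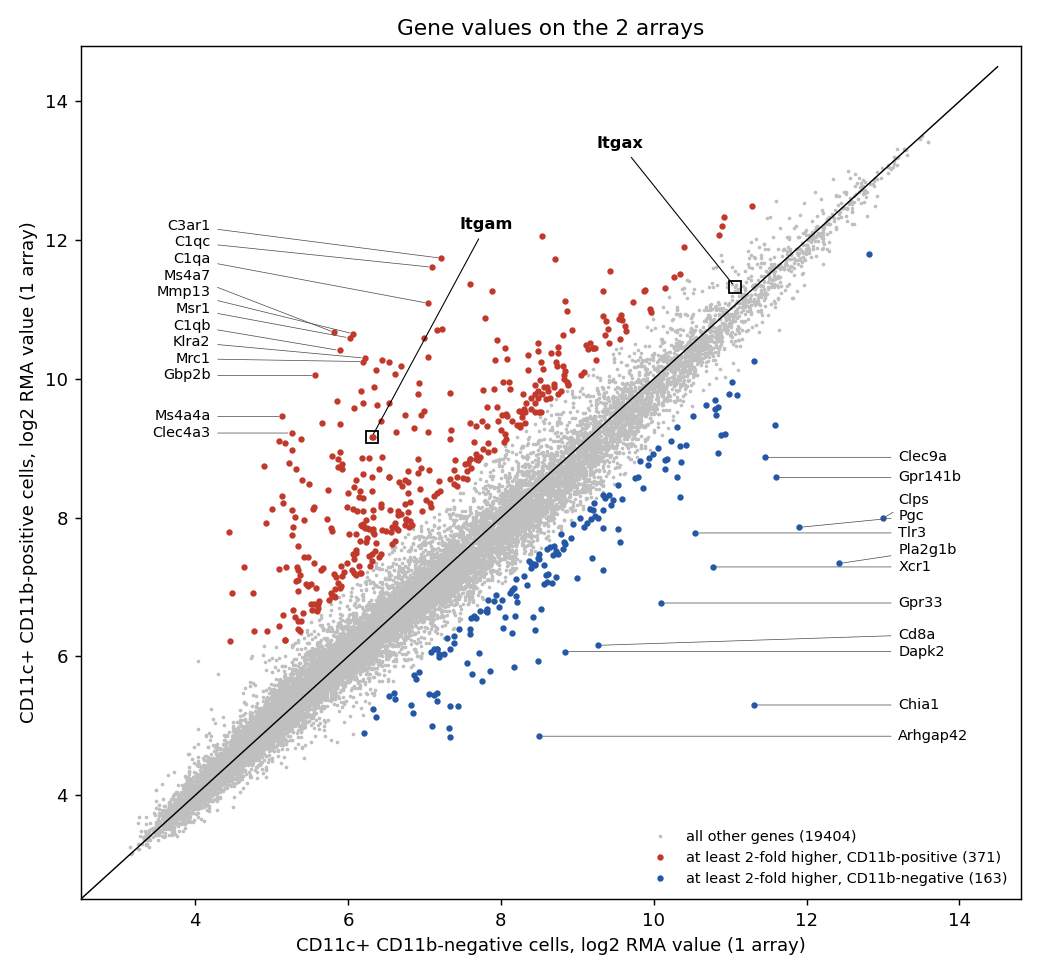
Each point is 1 gene, with its log2 RMA value in CD11b-negative cells on the x axis and in CD11b-positive cells on the y axis (1 array each); the line marks equal values, colours mark genes past the low filter that differ at least 2-fold, squares mark the sorted proteins' genes, and the 12 largest differences in each direction are labelled. The 371 genes higher in CD11b-positive cells reach differences of 4.85, and of the 163 genes higher in CD11b-negative cells, Chia1, Pla2g1b, Clps and Pgc lie farthest from the line on that side.

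The 12 genes with the largest differences towards CD11b-positive cells were Ms4a7, Mmp13, Msr1, C1qb, C3ar1, C1qc, Gbp2b, Ms4a4a, Klra2, Mrc1, C1qa and Clec4a3. Ms4a7, a membrane protein known from macrophages, was 5.82 in CD11b-negative and 10.67 in CD11b-positive cells, a 28.8-fold difference. Mmp13, a collagenase, differed 23.9-fold and Msr1, a scavenger receptor, 23.8-fold. The chains of the complement component C1q differed together, by 22.9-fold for C1qb, 22.8-fold for C1qc and 16.4-fold for C1qa. C3ar1, a receptor for a complement fragment, differed 22.9-fold. Mrc1, the mannose receptor, differed 16.6-fold. Gbp2b, an interferon-inducible GTPase, differed 22.3-fold, Klra2 16.9-fold and Clec4a3 15.6-fold, and Ms4a4a differed by 4.32 on the log2 scale. These last 4 belong to families of similar genes, and their probe sets could share signal with other members.

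In the opposite direction the 12 largest differences were those of Chia1, Pla2g1b, Clps, Pgc, Arhgap42, Xcr1, Gpr33, Cd8a, Gpr141b, Dapk2, Tlr3 and Clec9a. Chia1, an acidic chitinase, was 11.31 in CD11b-negative and 5.30 in CD11b-positive cells, a 64.4-fold difference. Pla2g1b, a secreted phospholipase, was 34.1-fold higher in CD11b-negative cells, Clps, the cofactor of pancreatic lipase, 32.2-fold and Pgc, a pepsinogen, 16.4-fold. Clps stood at 13.00 in CD11b-negative cells, near the top of the array's range. Arhgap42 was 12.6-fold higher in CD11b-negative cells by its brighter probe set, a difference of -3.65 on the log2 scale, against -2.72 by the mean of its probe sets. Xcr1, a chemokine receptor of type 1 conventional dendritic cells, was 11.2-fold higher, Gpr33 10.1-fold, Cd8a 8.63-fold, Gpr141b 8.11-fold and Dapk2 6.82-fold. Tlr3, the receptor for double-stranded RNA, was 6.77-fold higher and Clec9a, a receptor for dead cells, 5.98-fold higher.

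Genes known from type 1 conventional dendritic cells, the XCR1+ lineage that depends on Batf3 and Irf8, were lower in CD11b-positive cells as a group. Of the 20 measured, 11 were at least 2-fold higher in CD11b-negative cells, 9 lay within 2-fold and none was 2-fold higher in CD11b-positive cells. The median difference was -1.16, lower than in all 10000 random lists, whose middle 95% ran from -0.24 to 0.06. Irf8 was 10.88 in CD11b-negative and 9.19 in CD11b-positive cells, and Itgae, which encodes the CD103 integrin chain, was 10.84 and 9.59. Batf3, at 8.67 and 8.78, and Cd24a, at 12.53 and 12.28, differed little. CD11b-positive cells still showed values well above the array median for Clec9a, at 8.87, and above it for Xcr1, at 7.29.

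Genes known from type 2 conventional dendritic cells, the SIRPα+ lineage that depends on Irf4, were higher in CD11b-positive cells as a group, the population whose macrophage genes were also 7.26-fold higher at the median. Of 16 measured, 8 were at least 2-fold higher in CD11b-positive cells, 7 lay within 2-fold, and Clec12a was higher in CD11b-negative cells, at 9.33 against 7.24. The median difference was 1.02, higher than in all random lists. The largest differences were 13.5-fold for Mgl2, a galactose-binding lectin, and 5.50-fold for Tnfsf9, a T cell costimulator. Sirpa was 9.64 and 10.69 and Cd300a 9.20 and 10.45. Irf4, at 8.72 and 9.71, was 1.99-fold higher. Esam, at 5.48 and 5.42 below the low filter, and Notch2, at 9.32 and 9.02, did not follow the group.

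Macrophage and monocyte genes showed the largest shift of any of the 28 lists. All 26 measured members were higher in CD11b-positive cells, 19 of them at least 2-fold, with a median difference of 2.86 or 7.26-fold. Csf1r, the receptor for macrophage colony-stimulating factor, was 7.79 in CD11b-negative and 10.88 in CD11b-positive cells. Cx3cr1, the fractalkine receptor, was 6.93 and 9.94, and Fcgr1, which encodes the CD64 Fc receptor, was 6.44 and 8.87. Mertk, a receptor for apoptotic cells, differed 14.4-fold. The abundant genes Lyz2, at 11.65 and 12.18, and Cd63, at 10.89 and 12.21, were well expressed in both.

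Genes shared by both types of conventional dendritic cell did not stand apart. Their median difference was -0.14 (percentile 20.3 among random lists), while their mean was 0.0047. Of 15 measured, 13 lay within 2-fold. Zbtb46, a transcription factor of these cells, was 6.75 and 6.94, and Dpp4 was 11.41 and 11.18. Flt3, the growth factor receptor of dendritic cells, was 2.10-fold higher in CD11b-negative cells, and Cd93 was 7.16-fold higher in CD11b-positive cells. Plasmacytoid dendritic cell genes had a median difference of -0.19 over 11 members (percentile 25.3). Among them the gut-homing receptor Ccr9 was 3.66-fold higher in CD11b-negative cells, while Tcf4, at 9.23 and 9.02, Pld4, at 10.06 and 10.26, and Tlr9, at 7.34 and 8.03, lay within 2-fold.

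Genes known to increase as dendritic cells mature and migrate were modestly higher in CD11b-positive cells, where macrophage genes were 7.26-fold higher at the median. The median difference over 19 members was 0.58, higher than in all random lists, and 17 members were above 0, but only Stat4 and Pdcd1lg2 exceeded 2-fold, at 2.45-fold and 2.38-fold. Ccr7, the receptor for migration to lymph nodes, was 10.77 and 11.60, Cd86 11.96 and 12.10, and Marcks 11.23 and 11.85.

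Antigen presentation genes were abundant in both populations. Over 12 class II genes the median difference was 0.14 (percentile 99.3, but within the range of random lists not matched on expression), and 11 members lay within 2-fold. H2-Ab1 was 12.92 and 12.98 and H2-Aa 12.66 and 12.82. Lgmn, a lysosomal protease, was the exception, at 8.71 in CD11b-negative and 11.73 in CD11b-positive cells, and Ctss was 11.97 and 12.53. H2-K1 and H2-D1, which encode class I chains, were on the class I list but were not analysed here. All 13 measured class I genes lay within 2-fold, with a median difference of -0.23 that did not stand apart (percentile 5.06). Of these, Tap1 was 1.75-fold and Tap2 1.60-fold higher in CD11b-negative cells, while Psmb9 was 12.79 and 12.35 and B2m 12.71 and 12.82.

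**Figure D2:**
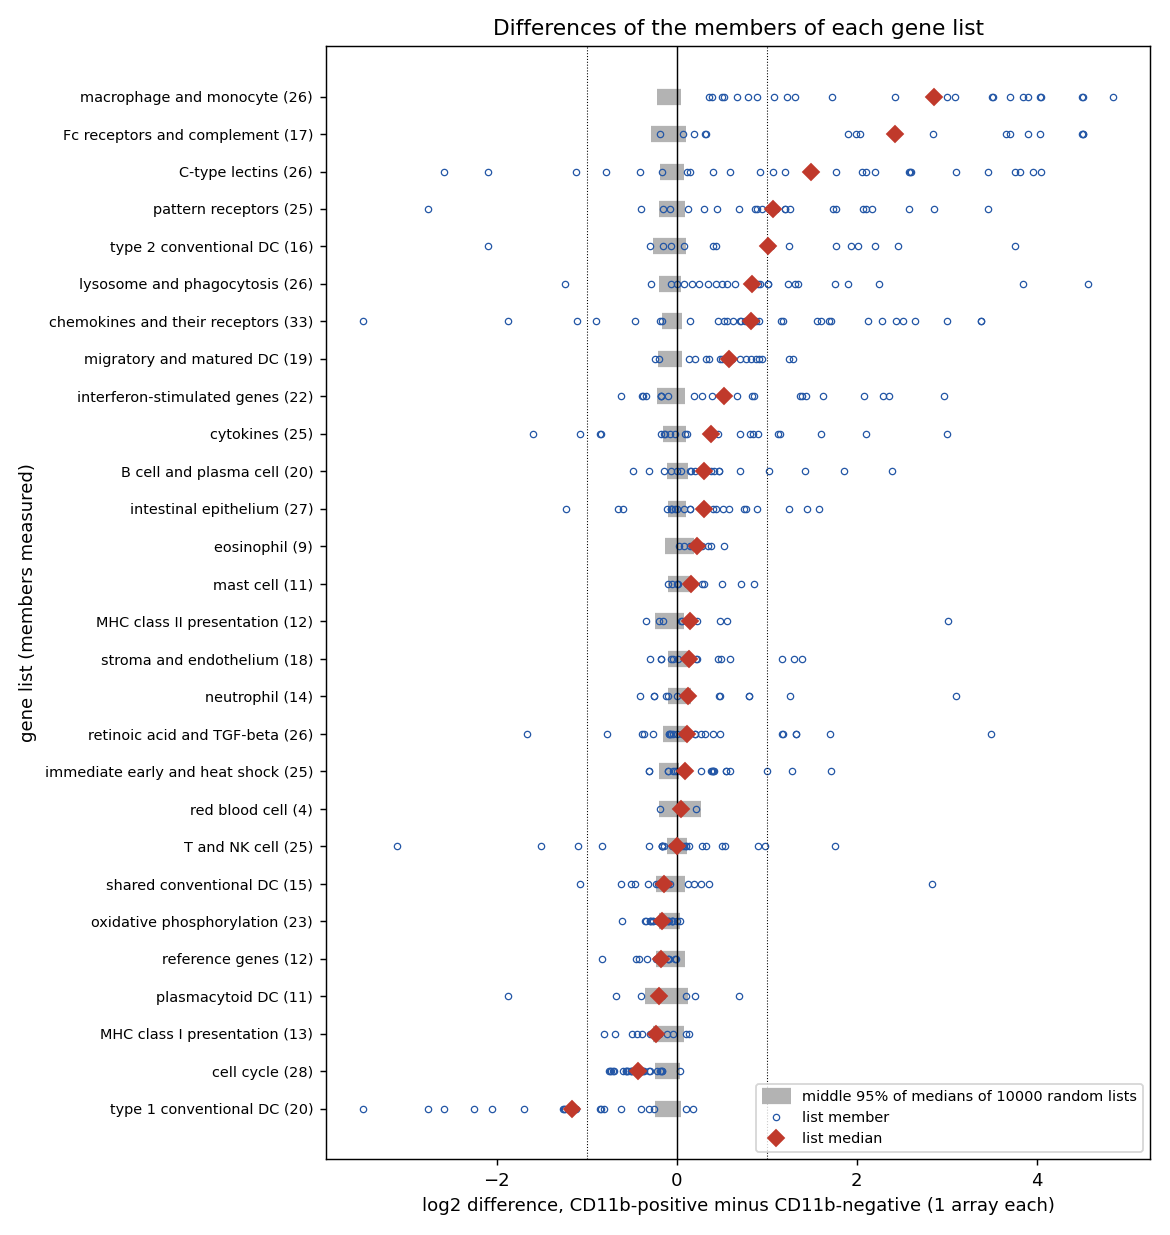
Log2 differences (CD11b-positive minus CD11b-negative, 1 array each) on the x axis for the members of each of the 28 gene lists on the y axis; circles are members, diamonds list medians, grey bars the middle 95% of medians of 10000 random lists matched on expression, and dotted lines mark 2-fold. The macrophage and monocyte list lies farthest right, with a median of 2.86, and the type 1 conventional dendritic cell list farthest left, with a median of -1.16.

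Receptors and secreted mediators of innate immunity were mostly higher in CD11b-positive cells, the population whose macrophage genes were also 7.26-fold higher at the median. Each of the following lists had a median above that of all 10000 random lists. Of 25 Toll-like and other pattern receptor genes, 14 were at least 2-fold higher in CD11b-positive cells (median 1.07). Clec4n differed 11.0-fold, Cd14, a coreceptor for lipopolysaccharide, 7.26-fold and Clec7a, a receptor for beta-glucan, 2.31-fold, Nlrp3 was 9.20 and 10.15, and Tlr3 alone was 2-fold lower. Of 26 C-type lectins, 15 were 2-fold higher and 3 were 2-fold lower, namely Clec9a, Clec12a and Ly75 (median 1.49). Of 17 Fc receptor and complement genes, 12 were 2-fold higher, among them Itgam, which only checks the labels, and none 2-fold lower (median 2.43), while Itgb2, the partner chain of CD11b and CD11c, was 9.78 and 9.60. Of 26 lysosomal and phagocytic genes, 10 were 2-fold higher and only the lipid scavenger Cd36 was 2-fold lower (median 0.83).

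Among 25 cytokine genes, 5 were at least 2-fold higher in CD11b-positive cells and 2 in CD11b-negative cells (median 0.38). Il10, an inhibitory cytokine, was 4.92 in CD11b-negative and 7.93 in CD11b-positive cells, 8.06-fold apart. Il1a differed 4.32-fold and Il1b, abundant in both, was 11.52 and 12.34. Il12b, the shared chain of interleukins 12 and 23, was 9.13 and 8.28, 1.80-fold higher in CD11b-negative cells. Il22ra2, the soluble antagonist of interleukin 22, was 2.10-fold higher in CD11b-negative cells, as was Ltb at 3.03-fold. Of 33 chemokine and chemokine receptor genes, 14 were 2-fold higher in CD11b-positive and 3 in CD11b-negative cells (median 0.83). Ccl12 differed 10.4-fold, Cxcr4 was 11.91 and 12.37 and Cxcl9 11.54 and 11.08. Of 22 interferon-stimulated genes, 8 were 2-fold higher in CD11b-positive cells (median 0.53), led by Ifit3 at 7.84-fold and Rtp4 at 5.13-fold. Ifit2, at 7.65 and 9.09, was 2.71-fold higher there. The list was mixed in direction, with 14 members above 0 and 8 below, among them Stat2, at 9.18 and 8.80.

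Genes of retinoic acid and TGF-beta handling were mixed. The median difference over 26 members was 0.11 (percentile 98.4), and this list fell within the random range after quantile normalisation or removal of an intensity trend. Aldh1a2, the enzyme that makes retinoic acid in gut dendritic cells, was 9.88 and 9.62. Itgb8, a chain of an integrin that activates TGF-beta, was 6.24 and 5.47, and Tgfb1 was 8.27 and 8.75. Thbs1, thrombospondin 1, was 11.2-fold, Tgfbi 3.27-fold and Tgfbr1 2.27-fold higher in CD11b-positive cells. Cyp26b1, which degrades retinoic acid, was 3.16-fold higher in CD11b-negative cells.

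Cell cycle genes were slightly lower in CD11b-positive cells, where macrophage genes were 7.26-fold higher at the median. Of 28 measured, 27 were below 0, Mki67 was 9.92 and 9.96, and none reached 2-fold, with a median difference of -0.42 that lay below all random lists. A count mostly below 0 was not particular to this list. All 12 reference genes, 21 of 23 oxidative phosphorylation genes and 11 of 13 class I genes were also below 0, with smaller medians that did not stand apart. Plk1 was 7.58 and 6.83, Rrm2 9.13 and 8.39, Top2a 10.82 and 10.46 (a difference of -0.10 by the mean of its probe sets) and Pcna 11.92 and 11.74. Immediate early and heat shock genes, which can change during tissue dissociation, had a median difference of 0.09 (percentile 99.7, but within the range of random lists not matched on expression), with Ier3 3.29-fold and Nfkbiz 2.43-fold higher in CD11b-positive cells and Hspa8 and Hsp90aa1 within 0.10 of equal. Oxidative phosphorylation genes had a median of -0.16 (percentile 10.5), with Cox6c at 12.90 in both populations, Cox5b at 12.36 and 12.32, Ndufb3 at 8.77 and 8.16 and Uqcrc1 at 8.62 and 8.27. Reference genes had a median of -0.17 (percentile 12.4), with Eef1a1 at 13.48 and 13.46, Actb at 13.59 and 13.42, Gusb 1.78-fold higher in CD11b-negative cells and Pgk1 at 11.58 and 11.13.

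Markers of other cells that the sort could have held were near the array median on both arrays for most lists. T and NK cell genes had a median difference of 0.01 and a mean of -0.076 over 25 members (percentile 54.3). The 3 members at least 2-fold higher in CD11b-negative cells were Cd8a, Cd8b1, at 2.85-fold, and Thy1, at 2.13-fold. Cd4 was 3.39-fold higher in CD11b-positive cells, Klrd1 was 9.99 and 9.83, and Cd3e was 6.55 and 6.50. B cell and plasma cell genes had a median of 0.30 over 20 members, above all random lists. Of these, Jchain, the joining chain of secreted antibodies, differed 5.24-fold and Bank1 3.63-fold, while Tnfrsf13c was 7.49 and 7.70. Intestinal epithelial genes had a median difference of 0.30 over 27 members (percentile 99.995), with median levels of 6.32 and 6.60. Fabp2 was 2.99-fold and Fabp1 2.73-fold higher in CD11b-positive cells, while Cdh17 was 2.35-fold higher in CD11b-negative cells. Lyz1, at 10.59 and 11.00, and Anpep, at 11.81 and 11.16, were bright in both, which does not by itself show an epithelial source. Only 16 of the 27 members passed the low filter, and Muc2, at 5.65 and 5.59, was among those that did not.

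Eosinophil genes had a median difference of 0.23 (percentile 99.1), with no member 2-fold apart, and fell within the random range over the 4 members past the low filter or by its mean. In that list Ccr3 was 5.71 and 6.24, Siglecf 6.81 and 7.16, Prg2 5.55 and 5.93 and Cebpe 6.45 and 6.53. Mast cell genes, of which only 2 of 11 passed the low filter, had a median of 0.16 (percentile 97.7), at the edge of the random range and within it after removal of an intensity trend, with Mcpt2 at 4.71 and 5.57, Mcpt1 at 4.18 and 4.90, Hdc at 5.99 and 6.49 and Gata2 at 5.93 and 6.21. Neutrophil genes had a median of 0.12 (percentile 92.1), with Mmp9 8.57-fold and Retnlg 2.39-fold higher in CD11b-positive cells and S100a9 at 6.43 and 6.91. Stromal and endothelial genes had a median of 0.14 (percentile 97.2), with Dcn 2.62-fold and Acta2 2.46-fold higher in CD11b-positive cells, Pecam1 at 8.67 and 9.26 and Col1a1 at 7.02 and 7.16. Only 4 red blood cell genes were measured, with a median of 0.06 (percentile 55.6), among them Slc4a1 at 6.27 and 6.09, Alas2 at 6.16 and 6.20 and Epb42 at 4.79 and 5.01. In all, 17 of the 28 lists stood above and 2 below the random lists, and 5 of the 17 fell within the random range under at least 1 alternative. The lists share members, such as the C1q chains, and are not independent of one another.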

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

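No direction of a list that stood apart or of a gene named by the rule and at least 2-fold apart was reversed by any alternative tried. The 2-fold counts stayed within 1.5 times under 3 rescalings, the mean of a gene's probe sets and 3 other low filters, with 379 to 546 genes in all. The split between directions moved from 69.5% of genes higher on the CD11b-positive array to at most 75.3%, after removal of a lowess trend. By construction the fold threshold moved the counts. At 1.5-fold there were 1470 genes, 752 higher on the CD11b-positive and 718 on the CD11b-negative array, and at 4-fold 136 genes, 111 and 25. Of 251 list values under alternatives, 233 kept their side of the random range. One of these alternatives was chosen after seeing the data, the Fc receptor and complement list without Itgam, the gene of the protein sorted on, which stayed above all random lists (median 2.235 over 16 genes, 11 of them 2-fold higher in CD11b-positive cells). The retinoic acid and TGF-beta list fell inside it after quantile normalisation (median 0.09) and lowess (0.085), and the mast cell list after lowess (0.13). The eosinophil list fell inside it over members past the low filter (0.29) and by its mean (0.24). Against random lists not matched on expression, the class II (0.14) and immediate early (0.09) lists fell inside, and the plasmacytoid (-0.19), class I (-0.23), oxidative phosphorylation (-0.16), reference gene (-0.17) and stromal (0.14) lists fell outside. The stromal list also stood apart after quantile normalisation (0.13), after lowess (0.14), over members past the filter (0.36) and by its mean (0.31), and the neutrophil list over members past the filter (0.81) and by its mean (0.43). The cause of these changes was not tested. Of 520 values of named genes, 3 moved beyond the scatter of probe sets, all with the mean of a gene's probe sets, for Arhgap42 (-2.72), Top2a (-0.10) and Wdfy4 (-0.93). No paired analysis was possible because each population has 1 array, and no replicate could be left out. Signal over background limits the dim lists, and only 2 of 11 mast cell genes passed the low filter.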

Other observations

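The tests of intestinal epithelium, of dilution by macrophages and of B cells, and the scan of gene families, were chosen after the results they bear on were seen; the other tests were written before theirs. The condition that a list with median levels under the low filter excludes a source only where every gene of the pattern stands at least 4 (log2) above it was also set after all values were seen. It moved B cells from argued against to open and left the reading of pancreatic acinar cells as it was. In the scan, 341 families of at least 5 genes sharing a symbol stem past the low filter were placed among 2000 random lists each. Of these, 59 lay outside the random range, where 17.1 are expected by chance if members were independent, which genes of a family are not. Probe sets of similar genes in a family could also share signal. The families higher in CD11b-positive cells are given beside a macrophage list that was also higher there, by 2.86 at the median. All 7 guanylate-binding protein genes were at least 2-fold higher in CD11b-positive cells (median 2.08), from 2.23-fold for Gbp5 through 4.56-fold for Gbp7 to 11.6-fold for Gbp4 and 22.3-fold for Gbp2b. Of 8 Ms4a genes 5 were 2-fold higher (median 1.65), including Ms4a6d at 13.5-fold. Of 8 matrix metalloproteinase genes 5 were 2-fold higher (median 1.31), with Mmp14 at 8.28-fold and Mmp12, already bright at 9.73, at 2.60-fold. The 8 integrin alpha genes with a numbered symbol past the low filter had a median of -0.63, with Itga8 3.20-fold, Itga6 2.33-fold, Itga1 2.11-fold and Itga3 2.04-fold higher in CD11b-negative cells, while Itga9 was 10.9-fold higher in CD11b-positive cells. The scan left out alpha chains with a lettered symbol, which went both ways, with Itgam 7.21-fold and Itgav 2.25-fold higher in CD11b-positive cells and Itgae 2.38-fold higher in CD11b-negative cells. Of 7 phospholipase A2 genes 4 were 2-fold higher in CD11b-positive cells (median 1.16), with Pla2g2d at 10.9-fold, and only Pla2g1b was 2-fold higher in CD11b-negative cells.

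Genes known from the stomach were uneven in level, some bright and some near the floor on both arrays. The labels give small intestine as the source, and whether stomach or adjoining duodenal tissue entered the preparation is not known from them. Gkn1, a gastrokine, was 10.54 in CD11b-negative and 10.06 in CD11b-positive cells, above 95.8% and 93.8% of all genes. Gkn2 was 10.18 and 9.93, Tff1 9.69 and 9.49, and Cblif, gastric intrinsic factor, 8.82 and 7.96, while the gastric lipase Lipf was 4.08 and 4.04, the pepsinogen Pga5 5.60 and 5.63 and Gast 6.56 and 6.69. Tff2 and Gkn3 were 3.43-fold and 5.10-fold higher in CD11b-positive cells, and the proton pump genes Atp4a and Atp4b were 2.68-fold and 2.14-fold higher in CD11b-negative cells. Xist was 11.19 and 11.31, and the Y-linked gene Eif2s3y 3.86 and 3.89. Outside the named genes, 5937 probe sets with no symbol and 849 with several passed the filter. Of these, 216 with no symbol and 23 with several were 2-fold higher on the CD11b-positive array, and 296 and 9 were 2-fold higher on the CD11b-negative array. Probe sets with no symbol thus leaned the other way from the named genes, of which 371 were higher on the CD11b-positive and 163 on the CD11b-negative array.

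The first pattern weighed is the 16.4-fold to 64.4-fold higher signal of Chia1, Pla2g1b, Clps and Pgc in CD11b-negative cells. Tables argue against RNA of pancreatic acinar cells, because 22 other acinar genes had a median difference of 0.04 and a median level of 5.58 in CD11b-negative cells, against 13.00 for Clps. They argue against a shift of intestinal epithelial genes as a whole, since 27 had a median of 0.30 in the opposite direction. Of these 27 genes, 3 were at least 2-fold higher in CD11b-positive cells and 1, Cdh17, was 2.35-fold higher in CD11b-negative cells. The rule for this test was written after the values were seen. Only 16 of the 27 passed the low filter, and their list's median level in CD11b-negative cells was 6.32, close to that filter. A shift of gastric genes as a whole is argued against too, since 16 had a median of -0.005 and none lay below -1.42. Gastric genes went both ways, with 2 at least 2-fold higher in each population, so their median cannot exclude a single kind of gastric cell. Gastric cells of a single kind, covered by that list or not, remain open. Expression by the CD11b-negative cells themselves also remains open and was not tested.

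The second pattern is the higher macrophage signal in CD11b-positive cells. The deposited arrays were already close, and 3 rescalings moved the median difference of all genes by only -0.01, 0 and 0.002. The median of the macrophage list stayed at or above 2.85 under them. This argues only against a scale difference or intensity trend left in the deposited values. These rescalings had little to remove and do not test the scaling done before deposit. Macrophages beside dendritic cells in the CD11b-positive sort are a candidate explanation, which would dilute genes shared by conventional dendritic cells. The median of that shared list, -0.14, lay inside the random range and does not decide it. The list is a poor measure of dilution, since it holds Itgax, the gene of CD11c, on which both populations were sorted. Its members at least 2-fold apart also went both ways, with Cd93 7.16-fold higher in CD11b-positive and Flt3 2.10-fold higher in CD11b-negative cells. Expression of the macrophage genes by CD11b-positive dendritic cells cannot be told apart from macrophages in the sort with 1 bulk array per population.

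The third pattern is the higher signal of Jchain, Igkv19-93, Cd22 and Bank1 in CD11b-positive cells, 9.06-fold for Igkv19-93 and 2.69-fold for Cd22. B cells cannot be excluded, since 12 B lineage genes had a median of 0.10 but median levels of 5.81 and 5.72, under the low filter, where a small change would not show. Of the CD79 chain genes, Cd79a was 5.02 on both arrays and Cd79b 2.04-fold higher in CD11b-positive cells. Antibody-secreting cells may contribute, as 11 immunoglobulin segments had a median of 0.89, above all random lists. Of these, 5 were at least 2-fold higher, among them Igha at 2.57-fold. The segments include Igkv19-93, a gene of the pattern itself, so this test is not fully independent of it. Secretory genes of antibody-secreting cells did not follow, with a median of -0.21 over 19 genes, most of them bright in both populations. The tests disagree and the source of the immunoglobulin signal remains open.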
